A study of Danio rerio with 4 samples.

How the data were processed

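RNA was measured in 4 libraries of whole zebrafish embryos, 2 given a control morpholino and 2 given a morpholino against srsf5a. Per the labels' protocols, the embryos were injected with 3 ng at the 1-cell stage and sorted by a fluorescent tracer. At 48 hours post fertilization 80 embryos per condition were lysed in TRIzol, RNA was purified again on a column, and 1 µg of it went into an Illumina TruSeq library. Groups and replicate numbers were taken from the sample titles. The labels call the samples biological replicates, but the 80 embryos are given per condition and not per library. Whether the 2 libraries of a group came from separate pools of embryos is therefore not known. The p-values measure the spread between these libraries.

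Per the submitters' processing notes, TopHat, HTSeq, DESeq2, Picard and the Zv9 genome build were used. Their versions, the annotation release, the strand setting of the counting and the step at which Picard was used are not given in the sources used here. The deposited per-sample files hold whole-number read counts for 32379 Ensembl gene identifiers, followed by summary totals. The authors' deposited table of the comparison holds a signal column (the mean of normalized counts over the libraries), log2 fold changes with standard errors, a score column (the Wald statistic) and p-values with adjusted p-values. The deposited signal column was recomputed from the deposited counts with DESeq2 size factors and differed by at most 4.95e-10. The authors' p-values and log2 values were used only to set the deposited result beside the one computed here.

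The summary totals were kept out of library sizes and tests. Reads assigned to genes made up 55.5% and 57.0% of the listed reads in control replicates 1 and 2, and 53.0% and 57.2% in srsf5a-morpholino replicates 1 and 2. In the same order, 32.1%, 29.0%, 34.2% and 29.6% had several alignments, 11.9%, 13.5%, 12.3% and 12.7% lay in no gene, and 0.499%, 0.531%, 0.443% and 0.526% were ambiguous. Genes with close copies therefore lost reads, and their values are uncertain. The 10 most abundant genes took 10.6%, 9.84%, 10.6% and 10.5% of gene counts. Totals of 15139525 to 36240893 counts put 3 counts, the upper limit that a count of 0 allows, at 0.0828 to 0.198 CPM. Such limits cover counting error only.

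Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.984 to 1.01), filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test with the morpholino group as the only term. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05. A further 5145 genes with counts were not tested. The common biological coefficient of variation was 12.9%. CPM values use TMM-scaled totals, and fold changes are log2, srsf5a morpholino over control. Their standard errors come from the same fit. Replicates differed by more than sampling noise. Chi-square per degree of freedom was 8.72 in the control pair and 13.5 in the srsf5a-morpholino pair, over genes with at least 10 counts. All 4 libraries were treated as separate samples, although such spread does not show that they came from separate pools of embryos.

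Gene symbols came from a table supplied with the data, which names 20603 of the identifiers, many in human-style capitals that paralogs can share. For 31 gene lists fixed before the data were examined, 1072 symbols were sought. Exact symbols matched 362 identifiers, older symbols 19, symbols differing only in case 320, and human-style names without the paralog letter 130. The match of dld, a Notch ligand gene, to DLD, a metabolic enzyme of the same name in capitals, was removed after the values had been seen. Lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The count adjusted over the list alone uses the list's own p-values.

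Named genes were chosen by a rule fixed before the data were examined. It takes srsf5a and srsf5b; the 8 largest increases and the 8 largest decreases among calls with a mean of at least 5 CPM in the higher group, both libraries beyond both controls and a symbol that is not a placeholder; up to 3 called genes with the lowest p in each list; and genes of the p53 pathway fixed beforehand, of which mdm2, cdkn1a and ccng1 are given. Some genes the rule takes are not reported here. Lists with no call may be given by 1 or 2 of their most abundant genes, and CRYBB1 is among these. The placeholder prefixes in the rule, meant for clone names, also left out real genes beginning with FO or CR. FOSL1 (3.71) and FOXQ1 (-1.25) would have ranked among the largest changes, whereas FOSL2 (1.99), FOS (2.02), CRX (-0.96) and FOXP2 (-0.72) would not. The rule was kept as written, and these genes are named after their values were seen.

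The procedure was tested on simulated counts for the 19917 tested genes with the real means and library sizes, with a known set of genes changed. The edgeR test found 13.4% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 83.3% of those changed 4-fold, and 13 of its 114 calls were false. With no gene changed, 13 genes were called. In these simulated counts the share of false calls was thus above the nominal 0.05. The adjusted p-values of edgeR may therefore understate the share of false calls in the real data as well. In the simulation with changed genes, 19660 genes passed the filter. There 1% of 200 random lists of unchanged genes had a camera p under 0.05. Genes were drawn independently of each other, so this rate does not cover lists whose genes vary together. In the real data the estimated correlation of the inflammation list was 0.549.

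Alternatives tried were DESeq2 size factors in the edgeR test, no filter or a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, limma-voom, other thresholds, and thinning to the shallowest total. Thinning was chosen after seeing the data. A search for junctions resembling the morpholino's target and a correction for GC content and gene length need a genome sequence, which was not used here, so neither was run. Splicing, and so the effect of the morpholino on srsf5a transcripts, was not analysed here, because the counts are per gene. Log2 values are given to 2 decimals and other values to 3 significant digits.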

Results

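Whole zebrafish embryos of the AB strain were injected at the 1-cell stage with 3 ng of a morpholino, an antisense oligomer that blocks splicing or translation, and their RNA was sequenced at 48 hours post fertilization. One group received a control morpholino (5'-CCTCTTACCTCAGTTACAATTTATA-3') and the other a morpholino against srsf5a (5'-GGATTCAGTCTCACCTCTCACTGCA-3'), read here as splice-blocking from its name in the labels, sMOsrsf5a. The gene srsf5a encodes a serine/arginine-rich splicing factor. Each group had 2 libraries, labelled as biological replicates, and 80 embryos were pooled per condition. Reads assigned to genes numbered 15139525 and 36240893 in control replicates 1 and 2, and 22739821 and 23950082 in srsf5a-morpholino replicates 1 and 2. Genes with at least 1 read numbered 22979, 23851, 23795 and 23681 in the same order. The series title asks about inadvertent RNA targets of morpholinos, and the comparison addressed here is which genes differed in level between embryos given either morpholino.

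The targeted gene, srsf5a (ENSDARG00000029818), was first read in every library. It stood at 335 and 286 CPM in the control libraries and at 335 and 368 CPM in the srsf5a-morpholino libraries, a log2 fold change of 0.18 ± 0.11 (SE) with an adjusted p of 0.424 in edgeR's quasi-likelihood test. A splice-blocking morpholino need not lower the total count of a gene, so this value neither checks the labels nor measures the block. The paralog srsf5b, listed as SRSF5 (ENSDARG00000027734), had a log2 fold change of 0.04 ± 0.10 (adjusted p = 0.866), which became -0.02 without control replicate 1 and -0.05 without srsf5a-morpholino replicate 2. Of 14 SR protein genes tested, SRSF9 alone passed the test, at -0.67 ± 0.11 (adjusted p = 0.0382). Its call ended without control replicate 1 (-0.61) and without control replicate 2 (-0.73). Adjusted over the list alone, 1 SR gene was lower, and the list did not pass camera (adjusted p = 0.442). None of 31 core spliceosome genes passed, by either adjustment, with PRPF8 at -0.12 and hnrnpa0b at -0.19 (camera adjusted p = 0.592).

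Genes higher in embryos given the srsf5a morpholino included 11 of 20 tested inflammation genes, 5 of 16 heat shock genes and 5 of 26 p53 pathway genes. Genes lower included GAD2, the only call among 37 neuronal genes, and the nuclear receptor genes RORB and NR2E3. The inflammation, heat shock, p53 pathway and neuronal lists passed camera with its preset correlation, and none of them with an estimated one (adjusted p = 0.577 to 0.589). Among 19917 genes tested, 395 passed a Benjamini-Hochberg adjusted p of 0.05, of which 242 were higher and 153 lower with the srsf5a morpholino. Of the higher genes 122 changed at least 2-fold, against 13 of the lower genes, and the median log2 fold changes were 1.01 and -0.72. In all 395, both srsf5a-morpholino libraries lay on the same side of both controls, as did 52.4% of all tested genes, where chance gives 33.3%. The count depended on the libraries used: it was 175 without control replicate 1, 33 without control replicate 2, 1156 without srsf5a-morpholino replicate 1 and 1410 without srsf5a-morpholino replicate 2. Without control replicate 2, 34 of the named genes lost their call, and without control replicate 1, 16 did.

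The genes with the largest increases under the naming rule were of several kinds. That rule left out FOSL1 (3.71) and FOXQ1 (-1.25), which would have ranked here and were singled out after their values were seen. cbx7a, a Polycomb group gene, went from 2.31 ± 0.05 to 27.3 ± 6.66 CPM (SD, n = 2), a log2 fold change of 3.56 ± 0.21 (SE). MMP9, a matrix metalloproteinase, reached 162 and 61.0 CPM against 12.6 and 7.50 in the controls (3.52 ± 0.48). The monocarboxylate transporter family gene SLC16A9 (2.97 ± 0.29), the sarcomeric gene tcap (2.77 ± 0.25), glycine N-methyltransferase GNMT (2.71 ± 0.12), the AP-1 gene JUNB (2.67 ± 0.17), the otoconial matrix gene oc90 (2.38 ± 0.29) and the cell cycle inhibitor cdkn1a (2.27 ± 0.16) followed. The largest decreases under the rule were those of the complement gene c9 (-1.70 ± 0.15), LDLRAD4 (-1.32 ± 0.14), the nuclear receptor genes RORB (-1.29 ± 0.13), NR2E3 (-1.18 ± 0.15) and THRB (-1.10 ± 0.11), the forebrain zinc finger gene FEZF1 (-1.10 ± 0.19), the transferrin gene tfa (-1.04 ± 0.16) and the retinol-binding gene RBP2 (-1.01 ± 0.14). Adjusted p in edgeR lay between 0.0017 for GNMT and 0.0412 for FEZF1. Without control replicate 2 the calls of MMP9 (3.14), oc90 (2.05), LDLRAD4 (-1.37), NR2E3 (-0.99), THRB (-1.11), FEZF1 (-1.04), tfa (-0.84) and RBP2 (-0.86) ended. Without control replicate 1 only FEZF1 (-1.15) among these lost its call.

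**Figure D1:**
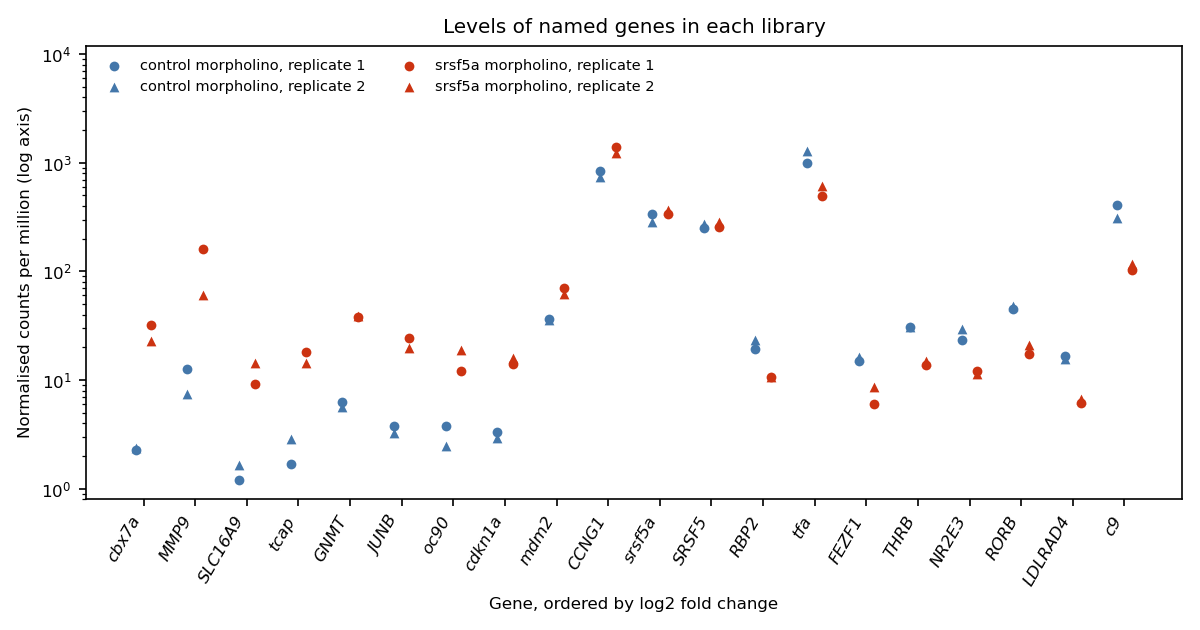
CPM (normalised read counts) on a log axis for the targeted gene and its paralog, the genes with the largest changes and 3 genes of the p53 pathway, with 1 point per library. Points of srsf5a overlap between the groups at 286 to 368 CPM, whereas MMP9 stands at 7.50 and 12.6 CPM in the controls and at 61.0 and 162 CPM with the srsf5a morpholino.

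Some genes of the p53 pathway rose. This list was included because the pathway is known to respond to morpholino injection. Of 26 genes tested, 5 were higher and 0 lower, and 9 were higher and 1 lower when adjusted over the list alone. In all, 16 lay above 0 and 10 below. cdkn1a, which arrests the cell cycle, had 3.34 and 2.94 CPM in the controls and 14.1 and 15.8 CPM with the srsf5a morpholino. mdm2, which encodes a ubiquitin ligase, changed by 0.86 ± 0.10 (adjusted p = 0.0189) and the cyclin gene CCNG1 by 0.74 ± 0.12 (adjusted p = 0.0361). The median of the list was 0.19, and camera placed it above other genes (adjusted p = 1.1e-04), a call lost with an estimated correlation (adjusted p = 0.577). The calls of mdm2 (0.84) and CCNG1 (0.64) ended without control replicate 2, and without control replicate 1 that of CCNG1 (0.83) did.

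The inflammation and acute phase list held the largest shift of any list. Of its 20 tested genes 11 were higher and 0 lower, 16 were higher when adjusted over the list alone, and the median log2 fold change was 1.23. JUNB was among them. A SOCS3 gene (ENSDARG00000025428), a feedback inhibitor of cytokine signalling, changed by 2.14 ± 0.16, and ATF3, a stress-induced transcription factor, by 1.73 ± 0.14. FOSL1, another AP-1 gene, changed by 3.71 and was singled out after its values were seen. The listed genes il1b, cxcl8a, il6, saa and hamp had no match and were not tested. Camera gave an adjusted p of 9.01e-31, and 0.577 with an estimated correlation. Of 14 interferon response genes, irf9 was higher (1.11 ± 0.18), 2 were higher when adjusted over the list alone, and the median was 0.59 (camera adjusted p = 0.015, and 0.627 with an estimated correlation). The interferon call ended without control replicate 2 (median 0.46), without srsf5a-morpholino replicate 1 (0.18) and with a filter of 1 CPM in 2 libraries (0.31). It also ended in 1 draw of libraries thinned to the shallowest total (0.52), an alternative added after seeing the data. Markers of neutrophils and macrophages did not pass as a list (21 tested, median 0.11, camera adjusted p = 0.0646). Among them the cathepsin gene ctss2.1 was higher (2.01 ± 0.24), and 4 were higher and 1 lower when adjusted over the list alone. The calls of irf9 (0.98) and ctss2.1 (1.72) ended without control replicate 2, as did that of irf9 without control replicate 1 (1.21).

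Complement genes, most of them made by the liver, moved in both directions. Of 15 tested, 2 were higher and 1 lower, and 4 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.422). c9 fell from 410 and 307 CPM in the controls to 103 and 117 CPM. c7b (2.27 ± 0.26) and c6.2 (1.34 ± 0.20), which encode other components of the membrane attack complex, rose. Without control replicate 2 the calls of c7b (2.31) and c6.2 (1.49) ended, and c6.2 also lost its call without control replicate 1 (1.23).

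In the heat shock list, mostly chaperone genes, 5 of 16 tested genes were higher and 0 lower, 8 were higher when adjusted over the list alone, and the median was 0.54. hspa1b was 4.29-fold higher (adjusted p = 0.0149), and other examples were hsp70.3 (1.38 ± 0.14) and HSPB1 (1.16 ± 0.14). The hsp70 genes are close copies, and since reads with several alignments were set aside their separate values are uncertain. Camera gave an adjusted p of 2.33e-10, and 0.577 with an estimated correlation. Of 21 genes of the integrated stress and unfolded protein response, the asparagine synthetase gene ASNS (0.83 ± 0.09) and the transcription factor gene atf4b (0.59 ± 0.09) were higher. Adjusted over the list alone, 7 were higher and 1 lower (median 0.11, camera adjusted p = 0.00196, and 0.627 with an estimated correlation). That list's call ended without srsf5a-morpholino replicate 1 (median 0.15). In the sterol synthesis list MSMO1, an enzyme of cholesterol synthesis, was higher (1.21 ± 0.16) among 19 tested, with 2 higher when adjusted over the list alone and a median of 0.22 (camera adjusted p = 0.00462, and 0.577 with an estimated correlation). Calls that ended without control replicate 2 were those of hsp70.3 (1.29), HSPB1 (1.09), ASNS (0.81), atf4b (0.56) and MSMO1 (1.27), and without control replicate 1 that of atf4b (0.60) did.

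Among 37 neuronal genes tested, 30 had a log2 fold change below 0, with a median of -0.28. GAD2, which makes the transmitter GABA, was the only call, falling from 89.5 ± 5.17 to 54.8 ± 2.79 CPM (SD, n = 2; -0.71 ± 0.10), and 7 were lower when adjusted over the list alone. Camera placed the list below other genes (adjusted p = 1.4e-06, and 0.589 with an estimated correlation). Of 28 neural progenitor and glial genes none passed, by either adjustment, with NOTCH3 at -0.30 and dlb at -0.12, while the list's median of -0.21 passed camera (adjusted p = 0.00167, and 0.627 with an estimated correlation). That call ended without srsf5a-morpholino replicate 1 (median -0.04). In photoreceptor genes (19 tested, camera adjusted p = 0.451) the cone transducin gene GNAT2 was higher (1.92 ± 0.30) and NR2E3, a photoreceptor nuclear receptor, was lower, the same counts as when adjusted over the list alone. The median of the photoreceptor list was -0.09 and its mean 0.03. The list matched 1 crx gene (ENSDARG00000011989), at -0.68 (adjusted p = 0.105 in edgeR). Another gene named CRX (ENSDARG00000043483), outside the list, was lower at -0.96 (adjusted p = 0.0219 in edgeR) and was singled out after its values were seen. The calls of GAD2 (-0.65), GNAT2 (1.59) and NR2E3 (-0.99) ended without control replicate 2.

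None of 22 lens genes passed over all genes, 8 were higher when adjusted over the list alone, and 19 lay above 0 with a median of 0.30 (camera adjusted p = 7.96e-06, and 0.577 with an estimated correlation). The crystallin gene CRYBB1 had 580 and 427 CPM in the controls and 828 and 778 CPM with the srsf5a morpholino (0.68 ± 0.15, adjusted p = 0.0725). In the epidermis list of 30 the keratin genes krt1-19d (1.12 ± 0.19) and krt18a.1 (0.77 ± 0.09) were higher. Adjusted over the list alone, 9 epidermal genes were higher and 1 lower (median 0.22, camera adjusted p = 5.39e-04, and 0.589 with an estimated correlation). Of 19 ionocyte genes the sodium pump subunit atp1a1a.3 (0.70 ± 0.11) was higher, with 4 higher when adjusted over the list alone and a median of 0.14 (camera adjusted p = 0.0186, and 0.577 with an estimated correlation). The ionocyte call ended without control replicate 1 (0.08) and without srsf5a-morpholino replicate 2 (0.05). Of 22 endothelial genes she (0.69 ± 0.12) was higher, with 5 higher when adjusted over the list alone and a median of 0.14 (camera adjusted p = 0.0208, and 0.577 with an estimated correlation). The endothelial call ended without control replicate 2 (0.08) and without srsf5a-morpholino replicate 1 (0.11). Without control replicate 2 the gene calls of krt1-19d (0.89), krt18a.1 (0.75), atp1a1a.3 (0.71) and she (0.62) ended, and without control replicate 1 those of krt18a.1 (0.79), atp1a1a.3 (0.69) and she (0.76) did.

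Structural and pigment lists changed little as sets. In the connective tissue matrix list (25 tested) a fibronectin gene, FN1, rose from 430 and 433 CPM to 1530 and 1914 CPM (3.99-fold), and no other member passed, even when adjusted over the list alone (camera adjusted p = 0.11). Of 36 cartilage and skeleton genes and2, which encodes a fin-fold fibre protein, was lower (-0.61 ± 0.11), with 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0646). Among 20 pigment cell genes tspan36 was higher (0.77 ± 0.09), also alone when adjusted over the list (camera adjusted p = 0.176). In skeletal muscle (32 tested) the junctophilin gene JPH2 was higher (0.68 ± 0.09), with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.217). No heart gene passed among 16, by either adjustment, with actc1a at 0.35 (camera adjusted p = 0.577). The calls of and2 (-0.50), tspan36 (0.79) and JPH2 (0.70) ended without control replicate 2, and they ended too without control replicate 1 (-0.71, 0.75 and 0.66).

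Of 21 embryonic red cell genes 16 lay below 0, with a median of -0.18. The globin gene hbae1.1 was lower (-0.88 ± 0.10), although near-identical globin copies make its separate value uncertain, and 6 genes were lower when adjusted over the list alone. Camera gave an adjusted p of 0.00425, and 0.627 with an estimated correlation, and the list's call ended without control replicate 1 (-0.06). Genes for yolk and liver secreted proteins went both ways, with 2 higher and 2 lower of 29 tested, and 6 higher and 4 lower when adjusted over the list alone. The lipid transfer gene MTTP was higher (0.68 ± 0.12), while tfa and the apolipoprotein gene apobb.2 (-0.83 ± 0.15) were lower. The median was 0.26 (camera adjusted p = 0.0208, and 0.589 with an estimated correlation), and the call ended without control replicate 2 (0.15). Of 13 pancreas genes none passed over all genes, with 4 higher and 1 lower when adjusted over the list alone and a median of -0.05 beside a mean of 0.38 (camera adjusted p = 0.277). The calls of hbae1.1 (-0.85), MTTP (0.60), tfa (-0.84) and apobb.2 (-0.79) ended without control replicate 2, and those of MTTP (0.75) and apobb.2 (-0.87) without control replicate 1.

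Housekeeping lists differed by small amounts. No gene of the cell cycle (37), cytosolic ribosome (64) or oxidative phosphorylation (45) lists passed, by either adjustment. hmga1a, a chromatin protein gene, had a log2 fold change of -0.05, mki67, a proliferation marker, one of -0.29 and RPL3 one of 0.01. The camera adjusted p was 0.672 for the cell cycle and 0.154 for the ribosome. Oxidative phosphorylation lay above other genes by a median of 0.11 (camera adjusted p = 0.00425, and 0.627 with an estimated correlation), with UQCRC1 at 0.22. Its call ended without control replicate 2 (0.08) and without srsf5a-morpholino replicate 1 (0.07). Transcripts of the mitochondrial genome made up 2.19% and 2.39% of gene counts in the controls and 2.73% and 2.42% with the srsf5a morpholino. None of their 13 genes passed, 1 was higher when adjusted over the list alone, and MT-CO1 stood at 0.17 (list median 0.17, camera adjusted p = 0.0208, and 0.627 with an estimated correlation). The mitochondrial call ended without control replicate 1 (0.09) and without srsf5a-morpholino replicate 1 (0.12). Of 35 circadian clock genes the repressor gene nfil3-5 was lower (-0.61 ± 0.09), also alone when adjusted over the list (camera adjusted p = 0.0646). Its call ended without control replicate 1 (-0.64) and without control replicate 2 (-0.58). Of 13 hatching gland genes none passed over all genes and 2 were higher when adjusted over the list alone, with he1.1 at 0.39 and XBP1 at 0.06 (camera adjusted p = 0.154).

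**Figure D2:**
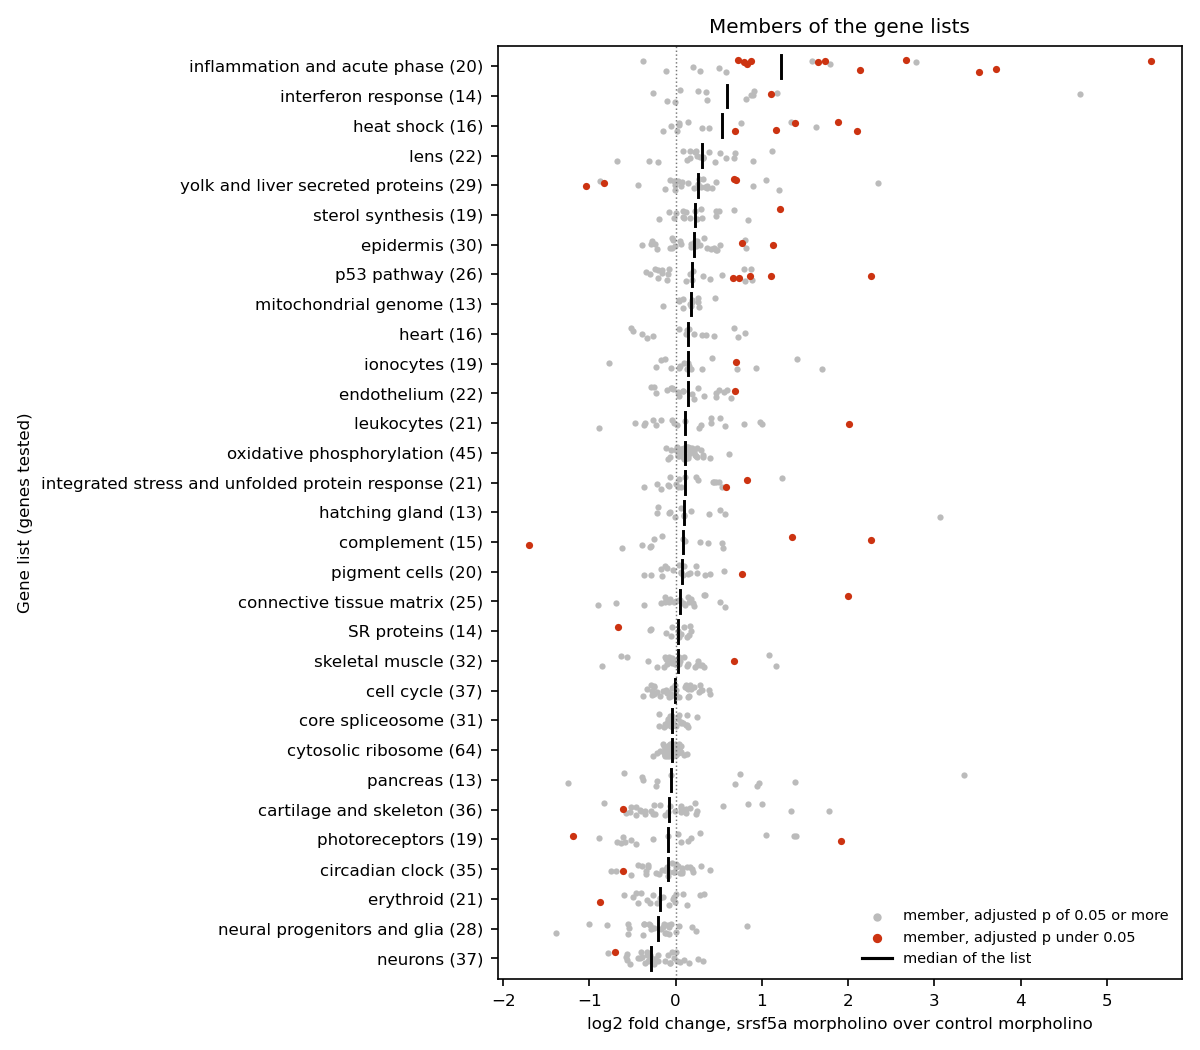
Log2 fold changes (srsf5a morpholino over control morpholino) of the tested members of all 31 gene lists, ordered by their median, with the number of genes tested in parentheses. Each point is a gene, red where its adjusted p was under 0.05, and black bars are medians. The inflammation and acute phase list has the highest median, 1.23, and the neurons list the lowest, -0.28.

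Across all 31 lists, 16 passed camera with its preset correlation of 0.01, 13 of them upward and 3 downward, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry 0 lists passed for a shift on balance to either side, with 8 at an unadjusted p under 0.05, whereas 24 passed its test for change in mixed directions. In these 4 libraries the list results rest on camera with its preset correlation. The size of the estimated correlation does not by itself account for every lost call. In the p53 list it was -0.032, below the preset 0.01, yet the unadjusted camera p was 0.0408 against 1.78e-05. The ionocyte list, at 0.004, had 0.108 against 0.00782. The estimated correlation and its test rest on the few residual degrees of freedom left by 4 libraries in 2 groups. A call lost in this way therefore shows neither that the genes of its list vary together nor that the list did not shift.

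The authors' deposited table, made with DESeq2, gives an adjusted p for 16425 genes and 1006 of them pass 0.05, with 515 higher and 491 lower. It also passes 383 of the 395 genes called here, and all 395 have the same sign in it. Across genes, which are not independent replicates, its log2 fold changes and those found here had a Spearman correlation of 0.968. In the authors' deposited table srsf5a has a log2 fold change of 0.16 (adjusted p = 0.554), cdkn1a one of 1.68 and mdm2 one of 0.77. The DESeq2 Wald test run here gave 2.26 for cdkn1a and 0.85 for mdm2. The deposited mean counts were recomputed from the same counts, so the smaller deposited values do not come from different counts. Their reason was not tested.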

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

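Thinning the libraries was chosen after seeing the data, and the other alternatives before. The count of 395 genes (242 higher, 153 lower) changed by more than 1.5 times under several of them. It was 956 (494 higher, 462 lower) with the DESeq2 Wald test, which also called 388 of the 395. It was 7 (7 higher, 0 lower) at an adjusted p of 0.01 in edgeR, where 4098 genes had an unadjusted p under 0.05, 1372 (748 higher, 624 lower) at 0.1, and 135 (122 higher, 13 lower) with at least a 2-fold change. Leaving out each library in turn gave 33 to 1410 genes, 31 to 702 higher and 2 to 708 lower. A lone library is assumed in these fits to vary like those of the other group. Of the 395, 139 were called without control replicate 1, 30 without control replicate 2, 392 without srsf5a-morpholino replicate 1 and all 395 without srsf5a-morpholino replicate 2. The share of higher calls, 61.3%, was 76.0%, 93.9% and 49.8% without control replicate 1, control replicate 2 and srsf5a-morpholino replicate 2, 100% at 0.01 and 90.4% with the 2-fold bound. The cause was not tested, apart from depth and spread in the last part. The count stayed within 1.5 times at 393 with DESeq2 size factors, 379 without a filter, 533 with a filter of 1 CPM, 417 with limma-voom and 526 after thinning. The thinned count is that of 1 draw, and 10 draws gave 381 to 551 genes with a median of 433.5.

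With the replicate number as a block the count was 1582 (865 higher, 717 lower), all 395 among them. Deviations of same-numbered libraries from their group means correlated at 0.456 across genes, but with 2 pairs this does not establish pairing. The block ended the call of the mitochondrial genome list (adjusted p = 0.0618, and up to 0.613 with a library left out) and of no other list or named gene.

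srsf5a was not called under any alternative run, with log2 fold changes of 0.07 to 0.29. SRSF5, never called, ranged from -0.051 to 0.125 with a library left out, reversing to -0.016 without control replicate 1 and to -0.051 without srsf5a-morpholino replicate 2. Of the 46 named genes called, 6 passed an adjusted p of 0.01 and 29 the 2-fold bound. At 0.05 they kept their call under each alternative normalization, filter, block and test run and without either srsf5a-morpholino library, while omitting a control library ended 16 calls (control replicate 1) or 34 (control replicate 2). The 16 list calls became 0 with camera's estimated correlation and 0 with fry. The interferon call also ended with the filter of 1 CPM (adjusted p = 0.0768) and after thinning in 1 draw (adjusted p = 0.0811). With these depths and 2 libraries per group, 13.4% of genes changed 1.5-fold in simulated counts were found, and which of the 2 sets that limit was not tested. The GC content and length correction and the junction search at 6, 7 or 8 mismatches were not run, for want of a genome sequence.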

Other observations

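The tests of transcription factor families, of one-carbon genes, of leukocytes, of a lone library, of delay, of neural tissue, of the spread within pairs and of the direction of neighbouring genes were chosen after the results were seen. Thinning was also added after seeing the data, although its bound was set before its own result was known, as were those for pairs of neighbouring genes and other splits. Genes named in this part beyond the fixed rule were chosen after their values were seen.

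Developmental transcription factors made up an unusual share of the genes that fell. By symbol stems of homeobox, Sox, Fox, LIM, nuclear receptor and related families, they were 33 of the 129 named genes that were lower (25.6%) and 1 of the 213 that were higher (0.469%), against 2.42% of genes not called (Fisher's exact test, two-sided, lower against higher, p = 1.4e-14). Examples were OTX2 (-0.95), LHX2 (-0.79), BCL11A (-0.89), ISL1 (-0.58) and PROX1 (-0.61), most of which act in brain and retina, while onecut3a rose (0.50). Of 406 such genes tested 324 lay below 0, with a median of -0.28 (camera p = 2.88e-18, and p = 0.111 with an estimated correlation). Names that share a stem but are not transcription factors, such as HERC1 and ROR1, were taken out by identity after values were seen, from a first count of 425, and none of them had been called. Before that the camera p was 2.44e-17 (0.11 with an estimated correlation). Leaving out a library changed the counts. They were 17 of 35 lower and 0 of 110 higher genes without control replicate 1, and 1 of 2 and 0 of 27 without control replicate 2. Without srsf5a-morpholino replicate 1 the contrast was smaller, at 53 of 439 lower and 9 of 539 higher genes, and without srsf5a-morpholino replicate 2 they were 100 of 594 and 1 of 591. The stems as first run missed nuclear receptor names such as NR2E3, which was noticed among the lower genes. With these added the count was 35 of 129 (Fisher's exact test, p = 1.43e-15), and that wider count is not independent of what had been seen. Neuronal genes (median -0.28, 30 of 37 below 0) and neural progenitor and glial genes (-0.206, 23 of 28 below 0) shifted by similar amounts. The shift of the progenitor and glial genes was smaller without srsf5a-morpholino replicate 1. That the families may have fallen together is thus a hypothesis, found and tested on the same libraries, and it was not separated from a lower level of neural genes at large.

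Genes of the methionine cycle and one-carbon metabolism were among those that rose. GNMT, which consumes S-adenosylmethionine, a MAT2A gene that makes it (adjusted p = 0.0158), cbsb (0.86 ± 0.10) and SHMT1 (0.74 ± 0.10) were higher, and 0 of the 30 tested passed as lower. In total 23 lay above 0 and 7 below, with a median of 0.23. A MTHFD1 gene (ENSDARG00000018266) stood at -1.36 ± 0.32 (adjusted p = 0.0783). The list was drawn up after these genes had been noticed and includes them, so its camera p of 5.77e-08 (0.0253 with an estimated correlation) is a hypothesis that the pathway may have risen, not independent evidence.

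The number of genes called fell when a control library was left out and rose when an srsf5a-morpholino library was. With all libraries thinned to 15139525 counts, the count without control replicate 1 was a median of 1.58 times the count without control replicate 2 over 10 draws, with a range of 1.28 to 4.26, against 5.3 without thinning. The ratio was thus lower in all 10 draws, but it lay on both sides of the bound of 1.5. In 1 draw more genes were called without control replicate 1 (440) than with all libraries (381). Whether the greater depth of control replicate 2 accounts for the whole difference cannot be told apart from other differences between the controls. A wider spread of the srsf5a-morpholino pair may account for the rise, since the biological coefficient of variation was 14.54% in that pair and 11.02% in the control pair.

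Of 20 inflammation genes 11 were higher with the srsf5a morpholino. A larger number of leukocytes is argued against as the whole cause only as far as the tested markers reach. Their median was 0.112, below the lower quartile of the inflammation list, 0.56. The markers mpx, mpeg1.1, mpeg1.2, mfap4, cxcr4b and csf1ra had no match and were not tested, and apoc1 is also on the yolk and liver list. A rise of some leukocytes is thus not excluded. An effect of a lone srsf5a-morpholino library is argued against as the whole cause for the inflammation list. Its lower quartile stayed above 0 without replicate 1 (0.343, median 0.892) and without replicate 2 (0.757, median 1.864). Direct effects of srsf5a loss, other RNA targets of the morpholino and injury or toxicity of injection remain open and untested, since no rescue, mutant or uninjected group was analysed here.

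Neuronal genes had a median of -0.28 with 1 of 37 called lower, and lens genes a median of 0.30 with 0 of 22 called. Camera calls both lists, and neither with an estimated correlation (adjusted p = 0.589 and 0.577). A uniform delay of development that lowered lens and neuronal genes alike is argued against for the lens genes. Their lower quartile was 0.164, and 19 of 22 lay above 0. How lens genes change with age was not measured here, and the lens list belongs to the pattern itself. A delay that acts on lens genes otherwise thus stays open. A smaller share of neural tissue could lower neurons and progenitors alike. Their medians, -0.28 and -0.206, lay within each other's interquartile range. The shift of the progenitor and glial list was smaller without srsf5a-morpholino replicate 1, as given above, so this likeness depends on that library. Without cell counts a smaller share and lower transcription cannot be told apart.

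Linked local differences between the pools are argued against as a source of many extra pairs of called genes beside each other on chromosomes, although a small excess is not excluded. Of 11688 genes placed by the order of the GRCz12tu annotation, 244 were called, and 7 neighbouring pairs were both called, against a mean of 5.06 in 10000 permutations (permutation p = 0.249). Without tandem copies there were 6 pairs against 4.88 (permutation p = 0.366). All 7 pairs moved the same way, against a mean of 2.79 such pairs when signed calls were permuted (permutation p = 0.0221), and 6 against 2.69 without tandem copies (permutation p = 0.0526). That test was chosen because the pairs had been seen to share a direction, so it decides nothing. The 4 libraries can be divided into groups of 2 and 2 in 3 ways. The real division, 1 of 3, called 395 genes. Replicate 1 against replicate 2 libraries gave 27 genes, and the crossed division gave 0. These 3 divisions are too few for a share under 0.05.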
